A study of Homo sapiens with 6 samples.

How the data were processed

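Total RNA of 6 J82 cultures was extracted with a column kit and sequenced on the BGISEQ-500, per the labels' protocols. The groups were 2 lines (tet-control and tet-ZFP36L1) at 3 times (0, 6 and 24 h of doxycycline), with 1 library in each, and samples were assigned from their titles. The submitters' processing notes name kallisto, DESeq2 and the build hg19, without versions.

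The deposited table of each sample lists 196354 Ensembl transcripts with a length, an effective length, estimated counts and TPM. The estimated counts are deposited values that need not be whole, since kallisto divides reads among transcripts by expectation maximisation. The deposited TPM values sum to 1000000 per library and are scaled for effective length and sequencing depth. The deposited effective length was checked in transcripts of at least 500 bases and equals the transcript length minus 179 in each library. Whether strand or a stated fragment length was used is not given in the sources used here, so reads of overlapping or antisense genes may not be separable.

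Transcripts were matched by identifier to GENCODE 29 on GRCh38, and 181854 of them matched. Unmatched transcripts held 5.12% to 5.47% of the estimated counts per library and were left out. The submitters' build differs, so gene positions are those of the GRCh38 annotation, and no coordinate was converted. Estimated counts were summed per gene and rounded to whole numbers, giving 19604891 to 20244775 counts per library over 52989 genes. Scaling used TMM factors (edgeR 4.0.16 in R 4.3.3) from genes with a mean count of at least 10. Values are log2(CPM + 0.5), which understates changes of genes with low counts, for 11908 genes with a mean count of at least 50 over the 6 libraries.

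With 1 library per group, no replicates estimate the spread within a group, and no count test of edgeR or DESeq2 was run. A model of line plus time would leave residual degrees of freedom, but it takes both lines to respond alike to doxycycline, and it was not fitted. The induction difference is the log2 change from 0 h in tet-ZFP36L1 minus that in tet-control. A gene was counted as lower or higher when both this difference and the line's own change were at least 1 on the log2 scale. The background is the same count with the lines exchanged. Intervals are 95% intervals from the counts, exact binomial for ZFP36L1 ratios and from the delta method elsewhere. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only.

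For 24 gene lists, written before the data were examined, the list's median was placed among 10000 random lists of the same size matched on mean count in 20 bins, as a description. A median was given for lists with at least 5 measured members. For 3' UTRs, the transcript of each gene with the highest mean TPM and an annotated stop codon was used, with a 3' UTR of at least 50 bases. Matched sets came from 10 by 10 bins of expression and 3' UTR length, and genes with no annotated 3' UTR were not searched. The genes named follow a rule written at the same time: ZFP36L1, ZFP36, ZFP36L2, HIF1A, CCND1 and E2F1, the 10 largest differences each way at each time among counted protein-coding genes of like sign at the other time, the 5 largest each way in tet-control at 24 h, the 10 largest each way between lines, and the 2 or 4 largest members of each list. The text describes part of these.

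Genes named were checked for 31-base words shared with matched transcripts of another gene. The unmatched transcripts took no part in this check, so sequence shared with them was not seen. Of 112 checked, 6 shared at least 50% of their words: Z83844.3, AL662899.2, NDUFC2-KCTD14, BORCS8-MEF2B, CD68 and ZACN. Their values are uncertain and, except for CD68, are not described. KIF24 and BAHCC1, which had 0 counts in a library, are not given a fold, and for OASL, with 0 counts in tet-control at 6 h, the text gives the difference at 24 h alone.

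The counting rule was tested on simulated Poisson counts with planted changes, run on 11792 genes. For tet-ZFP36L1 at 6 h against tet-control it recovered 44 of 44 genes lowered 4-fold and 46 of 49 lowered 2.46-fold, and counted 0 of 11599 unchanged genes. The simulation holds counting noise only, so this does not give an error rate for the real libraries. The percentile step was tested with 20 random sets of 40 unchanged genes, of which 0 fell outside the central 95%, and the same sets lowered by 0.3, of which 20 fell below it. The unchanged sets had a median percentile of 71.0, above the middle.

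The alternatives were DESeq2 size factors (DESeq2 1.42.0), plain CPM, the deposited TPM, other count minimums, other pseudocounts, a 1.5-fold threshold, other reference libraries, other 3' UTR choices, and 3 added after seeing the data: a 2-fold difference from tet-control at the same time as well, protein-coding genes alone, and leaving out genes that differed 2-fold between lines at 0 h. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.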

Results

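RNA was profiled in J82, an established human bladder cancer line, carrying either a doxycycline-inducible ZFP36L1 construct (tet-ZFP36L1) or a control construct (tet-control). ZFP36L1 is an RNA-binding protein of the ZFP36 family, which binds AU-rich elements in 3' UTRs and promotes decay of the bound mRNA. Each line was sampled after 0, 6 and 24 h with doxycycline, which was used at 1 µg/mL, giving 6 groups with 1 library each. The total of estimated counts per library lay between 20739025 and 21380480. No group had a replicate, no test between groups was run, and no p-value is given. Intervals are nominal 95% intervals of counting error only, approximate at low counts, and culture-to-culture variation is not in them.

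The first question was whether the labels match the level of ZFP36L1 (ENSG00000185650; GRCh38 chromosome 14, 68787660 to 68796253, minus strand). In tet-ZFP36L1 it stood at 220.2 CPM (counts per 1000000 counts, TMM-scaled) at 0 h, 3127 CPM at 6 h and 3133 CPM at 24 h. This was 14.2 times the line's own 0 h level at 6 h (interval 13.77 to 14.64) and 14.23 times at 24 h (13.8 to 14.67). The log2 difference from the change in tet-control was 3.89 and 4.01 with counts and 4.92 and 5.23 with the deposited TPM, outside these counting intervals. In tet-control it stood at 233.8, 223.3 and 206.0 CPM. At 0 h the ratio of the lines was 0.94 (0.9 to 0.98), so no excess of ZFP36L1 mRNA was seen in the inducible line before doxycycline. The annotated transcript with a 3' UTR of 211 bases held 4.6 estimated counts at 0 h and 33789.8 at 6 h in tet-ZFP36L1.

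**Figure D1:**
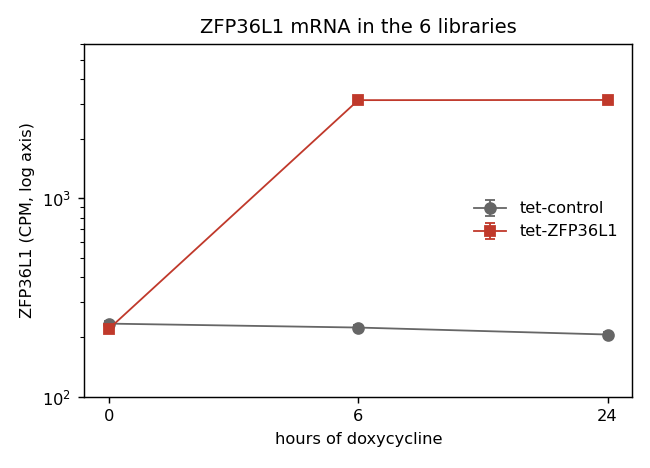
ZFP36L1 mRNA in CPM (log axis) against hours of doxycycline (evenly spaced) in tet-control (grey circles) and tet-ZFP36L1 (red squares), 1 library per point. Error bars are 95% Poisson counting intervals, smaller than most symbols; tet-ZFP36L1 stands at 3127 and 3133 CPM at 6 and 24 h, and tet-control stays between 206.0 and 233.8 CPM.

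The main comparison asked which mRNAs differed after induction beyond the change in tet-control. The induction difference is the log2 change from 0 h in tet-ZFP36L1 minus that in tet-control. At 6 h, 303 of 11908 measured genes were lower, with both this difference and the line's own change at least 2-fold, against 56 when the lines were exchanged. PLAU, the urokinase plasminogen activator (GRCh38 chromosome 10, 73909177 to 73917497), was at 364.5 CPM at 0 h and 36.03 CPM at 6 h in tet-ZFP36L1, a difference of -2.83 (-2.95 to -2.71). Of the genes named, ZNF512B was lowest at 6 h, at -5.74 (-6.36 to -5.12), but its difference at 24 h was -0.31. It stood at 64.0, 1.09 and 27.9 CPM at 0, 6 and 24 h in tet-ZFP36L1. TNFRSF11B, the decoy receptor osteoprotegerin, had a difference of -3.51 (-3.80 to -3.22), the cytokine IL6 had -3.40 (-3.55 to -3.25) and PHLDA2 had -3.20 (-3.57 to -2.84). Higher levels in tet-control at 6 h entered these differences, by 0.53 for TNFRSF11B, 1.56 for IL6 and 1.04 for PHLDA2, and the own changes in tet-ZFP36L1 were -2.98, -1.84 and -2.17. ZFP36L2, a family member, was at 62.3 CPM at 0 h and 12.8 CPM at 6 h, with a difference of -2.62 (-2.87 to -2.38). The lower genes had a median 0.32 above tet-control at 0 h, and 81 of the 303 started at least 2-fold above it, against 5.05% of all genes. The induction difference subtracts the 0 h difference of the lines, so choosing low values favours such genes by construction. Counting a gene only when it also differed 2-fold from tet-control at 6 h, a rule chosen after seeing the data, left 176 lower genes, and a pseudocount of 5 left 139.

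In the upward direction, 88 genes were higher at 6 h, against 85 with the lines exchanged, a background of nearly the same size, and a pseudocount of 5 gave 41. Some single genes in it were far higher: ROBO2, an axon guidance receptor, was at 5.06 CPM at 0 h, 484.4 at 6 h and 414.7 at 24 h in tet-ZFP36L1, and below 1 CPM in each tet-control library. KDM4A, a histone demethylase, was at 86.3, 1208 and 919.4 CPM at those times. GLE1, an mRNA export factor, was at 44.6, 587.1 and 519.9 CPM, and DLG3 at 13.5, 351.0 and 255.3 CPM.

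At 24 h, 593 genes were lower (33 with the lines exchanged) and 326 were higher (26 with the lines exchanged). With a 2-fold difference from tet-control at 24 h also required, a rule chosen after seeing the data, 386 and 228 were left, and with a pseudocount of 5 there were 366 and 110. The split depended on the scaling: plain CPM gave 384 lower and 488 higher, and the deposited TPM 404 lower and 390 higher. Those scalings moved the median difference of all genes at 24 h to 0.149 and 0.097, from -0.019. Lower at 24 h were NRP2, a semaphorin and VEGF co-receptor, at -3.15 (-3.49 to -2.82), and PHLDA2 at -3.57 (-4.00 to -3.14). Larger differences were those of EXOC8, at -5.14 (-6.69 to -3.60), and LUZP1, at -4.68 (-5.30 to -4.05). EXOC8 had 203, 440 and 3 counts at 0, 6 and 24 h in tet-ZFP36L1. Its interval is centred on the value with the pseudocount and leaves out the larger difference that the counts alone would give. For LUZP1 the change was 3.26 in tet-control and -1.42 in tet-ZFP36L1. The NF-kB pathway kinase MAP3K14 was at -3.52 (-4.42 to -2.63), from a low level of 2.80 CPM at 0 h; its change was 2.10 in tet-control and -1.42 in tet-ZFP36L1. Among counted protein-coding genes of like sign at 6 h, ROBO2 was highest at 6.33 (5.24 to 7.42). Next was OASL, an interferon-induced gene, at 5.43 (4.22 to 6.64), whose 6 h sign rests on 0 counts in tet-control. It stood at 1.13 CPM at 0 h, 1.14 at 6 h and 59.6 at 24 h.

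The tet-ZFP36L1 library at 24 h stood apart from the other libraries. It held 15694 genes with at least 10 counts, against 14514 to 14955 elsewhere, and its TMM factor was 1.115, against 0.941 to 1.006. Its induction difference also leaned with expression level: the fifth of genes with the lowest counts had a median of 0.23 and the fifth with the highest -0.21. Every value at 24 h below carries this, and random lists matched on expression are given for that reason.

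Of the genes counted at 6 h, 181 of 303 lower and 50 of 88 higher ones were counted at 24 h too. Both times use the same 0 h libraries, which by themselves can give shared genes. With the lines exchanged, 56 lower genes of 6 h and 33 of 24 h had 8 in common, and 85 and 26 higher genes had 13 in common, so these overlaps are not a measure of persistence. In a comparison without the 0 h libraries, the 303 lower genes of 6 h stood at a median of -0.84 from tet-control at 24 h (percentile 0.0 of matched gene sets). Across genes, Pearson's r was 0.60 and Spearman's rho 0.57. Through the shared 0 h libraries, counting noise alone gave 0.49 and 0.45 in 20 simulated draws. The covariance was 0.234, against 0.0113 simulated, a difference of 0.222. The simulation leaves out variation between cultures in the shared 0 h libraries, and genes are not independent replicates.

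**Figure D2:**
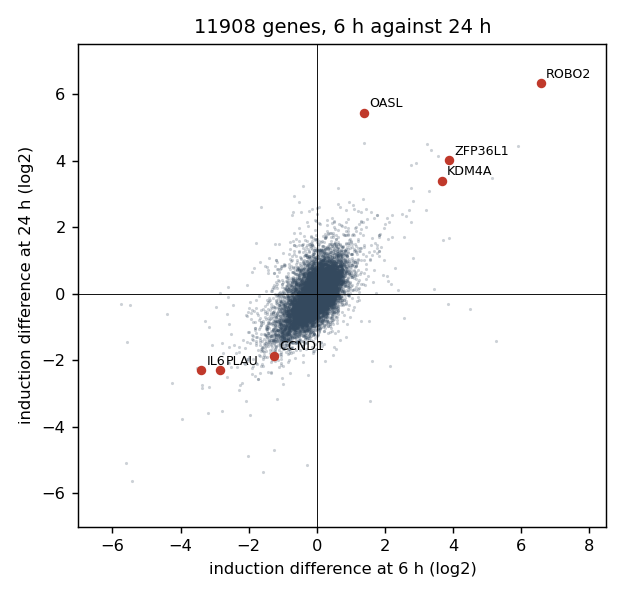
Induction difference (log2) at 6 h (x axis) against 24 h (y axis) for 11908 genes, 1 point per gene, with 7 genes in red. ZFP36L1, ROBO2 and KDM4A are high at both times, IL6, PLAU and CCND1 low at both times, and OASL is high at 24 h; its 6 h position rests on 0 counts in tet-control and on the pseudocount.

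Of the mRNAs listed beforehand as targets of ZFP36-family proteins, 32 of 44 measured members were at least 1.5-fold lower at 6 h and 1 was higher. Among all genes, 14.3% were lower and 7.0% higher by that size. At 24 h, 28 members were lower and 3 higher, and among all genes 17.4% were lower and 13.9% higher. The list's median difference was -1.21 at 6 h and -0.96 at 24 h, at percentile 0.0 of 10000 expression-matched random lists at both times. The list stood 0.40 above tet-control at 0 h and its median change in tet-control at 6 h was 0.28, both of which enter the difference; the line's own median change was -1.03 at 6 h and -1.18 at 24 h. Of its measured members, 15 are also on the list of NF-kB-driven cytokines, and the other 29 had medians of -0.83 and -0.89. CDKN1A, the cell-cycle inhibitor p21, stood at -2.58 (-2.78 to -2.38) at 6 h and -2.07 (-2.26 to -1.88) at 24 h. HIF1A, the hypoxia-inducible transcription factor, was at 395.4 CPM at 0 h, 250.0 at 6 h and 161.8 at 24 h. Its differences were -0.83 (-0.90 to -0.76) and -1.21 (-1.28 to -1.13).

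NF-kB-driven cytokines and chemokines had a median difference of -1.92 at 6 h, with 22 of 26 members lower and 0 higher. At 24 h the median was -0.59, with 13 lower and 5 higher. The percentile was 0.0 at both times. The median change in tet-control at 6 h was 0.42, which enters the difference, and the own change of tet-ZFP36L1 was -1.25. These genes did not start level: the list's median was 0.98 above tet-control at 0 h, -0.46 from it at 6 h and 0.45 above it at 24 h. IL6 was at 162.5 CPM in uninduced tet-ZFP36L1 and 44.6 in tet-control. IL1B was at 1052 CPM in uninduced tet-ZFP36L1, 87.8 at 6 h and 81.9 at 24 h, and at 0.94 CPM in tet-control at 0 h. CSF3 was at 38.1, 4.20 and 6.77 CPM, against 0.35 in tet-control at 0 h.

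**Figure D3:**
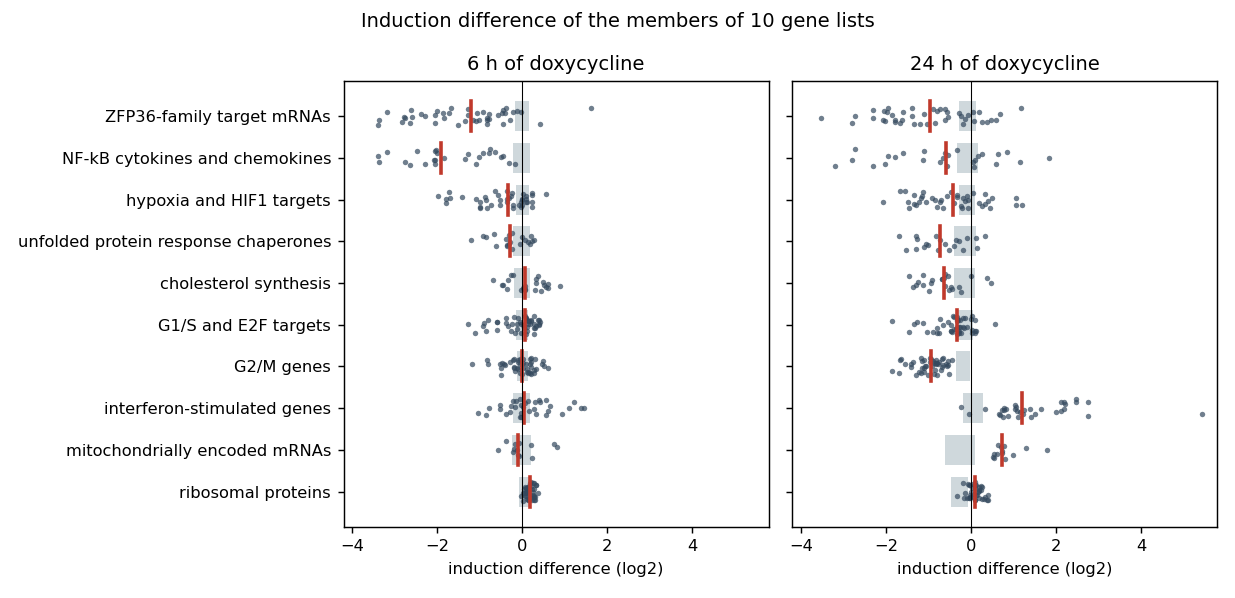
Induction difference (log2, x axis) of the measured members (points) of 10 gene lists at 6 h (left) and 24 h (right). Red lines are list medians and grey bands hold the central 95% of medians of 10000 expression-matched random lists; the ZFP36-family target list has medians of -1.21 and -0.96, and interferon-stimulated genes 0.05 and 1.20.

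Hypoxia and HIF1 targets were lower as a group, with medians of -0.33 at 6 h (percentile 0.01) and -0.43 at 24 h (percentile 0.05). Of 42 members, 15 were at least 1.5-fold lower and 0 higher at 6 h, and 19 were lower and 3 higher at 24 h. The list's median was 0.11 above tet-control at 0 h (percentile 98.61), -0.20 from it at 6 h and -0.36 at 24 h. Housekeeping genes had a median difference of -0.09 at 6 h and -0.48 at 24 h (percentile 1.55). A 24 h median of this size was therefore not particular to hypoxia targets. The glucose transporter SLC2A1 was at -1.78 (-1.91 to -1.65) and -2.07 (-2.20 to -1.93), and the growth factor VEGFA at -1.72 (-1.94 to -1.49) and -1.68 (-1.93 to -1.43). SLC2A1 started at 230.6 CPM in tet-ZFP36L1 against 70.7 in tet-control, and stood at -0.08 and -0.37 from tet-control at 6 and 24 h. VEGFA started 0.86 above tet-control and stood at -0.86 and -0.82 from it. LDHA, lactate dehydrogenase A, was at 0.11 (0.08 to 0.14) at 6 h, or -0.02 with the deposited TPM, and at -1.48 (-1.51 to -1.45) at 24 h.

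Cell-cycle genes differed mainly at 24 h. G2/M genes had a median of 0.00 at 6 h and -0.93 at 24 h (percentile 0.0), where 40 of 46 were lower and 0 higher. In tet-control the list was 0.19 above 0 h at 24 h (percentile 100), which enters that difference. The own change of tet-ZFP36L1 at 24 h was -0.71 (percentile 0.0), with 33 members lower. UBE2C, a ubiquitin-conjugating enzyme of mitosis, was at -1.85 (-1.93 to -1.76), the kinase PLK1 at -1.70 (-1.81 to -1.58) and the kinase AURKA at -1.64 (-1.73 to -1.56). G1/S and E2F targets had a median of 0.06 and a mean of -0.09 at 6 h (percentile 75.81). At 24 h their median was -0.33 (percentile 1.24), or -0.15 with the deposited TPM, and that of housekeeping genes was -0.48 (percentile 1.55). CCND1, which encodes cyclin D1, was at 859.3 CPM at 0 h, 310.0 at 6 h and 221.1 at 24 h, with differences of -1.27 (-1.32 to -1.21) and -1.86 (-1.92 to -1.81). E2F1 was at -0.93 (-1.08 to -0.77) and -0.80 (-0.94 to -0.66). RRM2, a subunit of ribonucleotide reductase, was at -1.45 (-1.51 to -1.40) at 24 h, of which 0.35 was its rise in tet-control. Of 5 measured replication-dependent histone genes, the median was -0.17 and -0.02, within the random range.

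Interferon-stimulated genes had a median of 0.05 at 6 h (percentile 72.68) and 1.20 at 24 h (percentile 100), where 31 of 34 members were higher and 0 lower. Beside OASL, IFI44 was at 2.76 (2.09 to 3.43). This list's median was already 0.45 above tet-control at 0 h. Mitochondrially encoded mRNAs had a median of -0.09 at 6 h and 0.73 at 24 h (percentile 100), with MT-ATP8 at 1.78 (1.33 to 2.23). Ribosomal protein mRNAs stood at 0.18 and 0.10 (percentiles 99.56 and 100), where random lists of like expression had a median of -0.28 at 24 h. Their own change in tet-ZFP36L1 at 6 h was 0.06, within the random range, and -0.13 in tet-control.

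Unfolded protein response chaperones had medians of -0.29 at 6 h (percentile 0.7) and -0.72 at 24 h (percentile 0.0), with MANF at -1.53 (-1.66 to -1.40) at 24 h. The own change of this list in tet-ZFP36L1 was -0.09 at 6 h, within the random range (percentile 15.62), and -0.65 at 24 h (percentile 0.01). Cholesterol synthesis genes had medians of 0.07 and -0.64 (percentile 0.05), with HMGCS1, the enzyme that makes HMG-CoA, at -1.46 (-1.56 to -1.36) at 24 h, of which 0.78 was its change in tet-control. In tet-control the cholesterol list was itself 0.45 above 0 h at 24 h, which enters that difference, and the own change of tet-ZFP36L1, -0.21, lay within the random range (percentile 23.92). Immediate early genes were at -0.29 (percentile 0.89) and -0.07, housekeeping genes at -0.09 and -0.48 (percentile 1.55), and 5 basal urothelial genes at -0.82 (percentile 0.45), or -0.26 with a pseudocount of 5, and -0.33. At 6 h the immediate early list had a median change of 0.23 in tet-control and 0.04 in tet-ZFP36L1, and the basal list 0.44 and -0.30, both within the random range in tet-ZFP36L1 (percentiles 64.57 and 9.39). At 24 h the basal difference was within the random range (percentile 23.48), with 2 members lower and 2 higher. The basal list's own median change in tet-ZFP36L1 was then 0.59 (percentile 99.44). Within the random range at both times were targets of the integrated stress response (-0.10 and -0.28), p53 targets (-0.16 and -0.09) and nuclear-encoded oxidative phosphorylation genes (0.15 and -0.23). The same held for extracellular matrix and mesenchymal genes (-0.05 and -0.14), 10 luminal urothelial genes (0.03 and 0.10) and CCR4-NOT and mRNA decay factors (0.05 and -0.08). For 2 of these lists the own changes in tet-ZFP36L1 lay outside the random range. They were 0.33 and -0.35 for integrated stress response targets (percentiles 100 and 0.68), where tet-control changed by 0.53 and -0.03. For extracellular matrix genes they were 0.26 and -0.33 (percentiles 99.77 and 1.35), against 0.21 and -0.05 in tet-control. With plain CPM the medians at 24 h of the immediate early, p53, histone, extracellular matrix and CCR4-NOT lists were positive, and the mean of the extracellular matrix list at 6 h was 0.07, against a negative median.

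Whether the difference went with AU-rich elements was examined in 10475 protein-coding genes with an annotated 3' UTR. Genes without the 7-mer TATTTAT had a median difference of 0.08 at 6 h, 1744 genes with 1 copy had -0.23, and 964 genes with 2 or more copies had -0.42. Gene sets matched on expression and 3' UTR length gave -0.13 (range -0.16 to -0.10) for the last class. At 24 h the medians were 0.05, -0.24 and -0.36, and matched sets gave -0.06 (range -0.10 to -0.01) for the last class. With the deposited TPM the 24 h medians were 0.16, -0.09 and -0.18, matched sets gave 0.09, and 11.5% of the last class had a difference of -1 or lower. Of the 964 genes, 14.9% had a difference of -1 or lower at 6 h and 17.5% at 24 h, against 2.8% and 4.2% of genes without the element. These shares are not matched on length: the median 3' UTR had 2966 bases in the 964 genes and 553 in those without the element. In tet-control the same 964 genes had median changes of 0.06 at 6 h and -0.07 at 24 h. These are small, but they enter the difference and lay outside the matched ranges. Those ranges were 0.00 to 0.05 at 6 h (percentile 99.69) and -0.06 to -0.04 at 24 h (percentile 0.07). In 140 genes with 2 or more copies of the 9-mer TTATTTATT the medians were -0.47 at 6 h and -0.37 at 24 h. The permuted 7-mers TTATATT and ATTTTTA, at 2 or more copies, went with -0.26 and -0.20 at 6 h and -0.27 and -0.21 at 24 h, also at percentile 0.0 of their matched sets. Of their genes, with median 3' UTRs of 3229 and 2882 bases, 8.3% and 7.3% had a difference of -1 or lower at 6 h. At 24 h these shares were 10.9% and 9.4%.

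**Figure D4:**
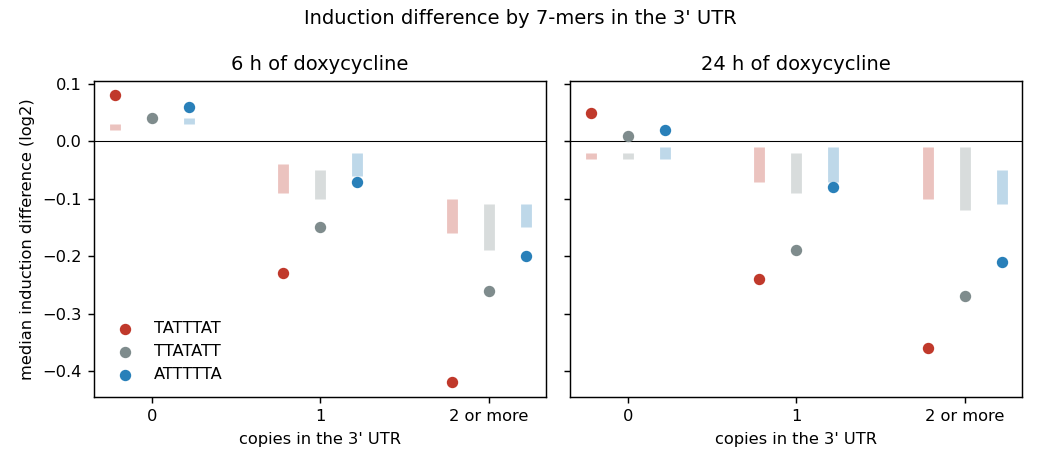
Median induction difference (log2, y axis) of genes by the number of copies of a 7-mer in the 3' UTR (x axis) at 6 h (left) and 24 h (right). Points are observed medians and pale bars the central 95% of sets matched on expression and 3' UTR length; with 2 or more copies, TATTTAT has -0.42 and -0.36, and its permutations lie between -0.20 and -0.27.

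Changes in tet-control showed what doxycycline, time and library noise did without the transgene. At 6 h, 265 genes were at least 2-fold lower and 289 higher than at 0 h, and at 24 h 51 and 45. With a pseudocount of 5 these counts were 48 and 123 at 6 h and 13 and 13 at 24 h. Several lists moved alike in both lines at 6 h. Mitochondrially encoded mRNAs were 0.89 above 0 h in tet-control and 0.98 above in tet-ZFP36L1, and mitochondrial transcripts made up 2.92% and 2.45% of gene counts, against 1.54% and 1.47% at 0 h. Targets of the integrated stress response were 0.53 and 0.33 above 0 h, with SLC7A5, an amino acid transporter, at 329.5 CPM at 0 h and 677.3 CPM at 6 h in tet-control. G1/S genes had median changes of -0.23 and -0.27. Among the largest changes in tet-control at 24 h were those of 2 transcription factors: MITF was at 23.5 CPM at 0 h and 3.44 CPM at 24 h, and TEAD1 at 1.99 and 43.8 CPM. In tet-ZFP36L1, under the same doxycycline, MITF was also lower, at 6.43 and 2.75 CPM. TEAD1 stood at 20.8 and 12.45 CPM there, so its rise was not shared by that line.

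The lines also differed irrespective of doxycycline. At each of the 3 times, 344 genes were at least 2-fold higher in tet-ZFP36L1 and 143 at least 2-fold lower, or 168 and 68 with a pseudocount of 5. PADI2, a protein arginine deiminase, was at 913.8 CPM in tet-control and 37.6 in tet-ZFP36L1 at 0 h, and NPNT at 572.0 and 16.8 CPM. SERPINB2, a plasminogen activator inhibitor, was at 0.45 and 120.4 CPM, and FLI1 at 1.09 and 41.9 CPM. Few markers of other cell types passed the count minimum: 1 of leukocytes, 2 of endothelium, 1 of fibroblasts and muscle, and 3 of neurons. CD68 was at 10.8, 15.03 and 28.2 CPM in tet-ZFP36L1, and shares most of its sequence words with other genes. ENG was at 103.9, 116.8 and 107.6 CPM, COL1A1 at 11.9, 19.1 and 13.9 CPM, and the neuronal tubulin TUBB3 at 127.5, 61.7 and 30.5 CPM.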

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

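All tests in this part were chosen after the values they bear on had been seen.

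MAP3K14 was at least 2-fold lower than 0 h in both induced tet-ZFP36L1 libraries and at least 1.5-fold higher than 0 h in both tet-control libraries, with an induction difference of -3.52 at 24 h. PLEKHG1 went the opposite way, higher in both induced libraries and lower in both tet-control libraries, with a difference of 4.51 (3.51 to 5.51) at 24 h. It started from 11 counts (0.54 CPM) in tet-ZFP36L1 at 0 h, near the pseudocount, against 116 counts (5.76 CPM) in tet-control. Its interval leaves out the value from the counts alone, since it is centred on the value with the pseudocount. Neither difference between the lines was tested, since each group is 1 library. Among 2016 transcripts with no match in the annotation, which the report does not use, 126 differed at least 2-fold with induction at both times (55 lower, 71 higher), against 97 with the lines exchanged.

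Genes counted as lower tended to start high in the uninduced tet-ZFP36L1 library, which their choice by a change from 0 h favours by construction. A return from a high or noisy 0 h value alone would leave them near or above tet-control at the other time, whose libraries took no part in choosing them. The values argue against it as the whole cause for the genes as a set: those lower at 6 h stood at a median of -0.84 from tet-control at 24 h, and those lower at 24 h at -0.79 at 6 h, both at percentile 0.0 of matched gene sets. For single genes it stays open, since 77 of the 303 and 82 of the 593 stood at or above tet-control at the other time. The NF-kB cytokine list at 24 h goes with it (0.45). It stays open for that list at 6 h (-0.46) and for the ZFP36-family target list at 24 h (-0.45), which were close to tet-control but low among matched random lists (percentiles 0.03 and 0.13).

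The tet-ZFP36L1 library at 24 h held more genes and had the largest TMM factor. It had the fewest gene counts of the 6, with a difference of -465444 from the mean of the other 5, so depth does not account for it. For cells of another type, 0 markers of any of 4 lists reached 5 CPM and 4 times the 0 h level, which argues against leukocytes, endothelium, fibroblasts and neurons but not against other types. An effect of induction, a difference of this culture or library preparation and a small share of other cells all remain possible explanations. With 1 library they could not be told apart.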

How the results depend on the processing

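The alternatives that also require a 2-fold difference from tet-control at the same time, or leave out genes that differ 2-fold between lines at 0 h, or count protein-coding genes alone, were chosen after seeing the data. Of 110 recomputed gene counts, 60 stayed within 1.5 times the main count and 50 did not; of 200 list medians 194 moved by less than the spread of random lists and 6 by more. Of 1060 values of other named genes, 894 stayed within their counting interval, 164 moved further, some of them small values that passed 0, and 2 values of at least 1.5-fold changed sign: SHH at 24 h, 0.01 with a pseudocount of 5, and COL1A1 at 24 h, -0.04 with the deposited TPM. The cause of these shifts was not tested, except that filters and thresholds change the counts by construction.

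Counts are given as lower, then higher. For induction, a minimum mean count of 10 gave 163 higher at 6 h and 527 at 24 h, no filter 195 and 606, and a minimum of 200 gave 45 and 153. In tet-control a minimum of 10 gave 498 higher at 6 h and 118 and 126 at 24 h, no filter 419 and 590 at 6 h and 148 and 169 at 24 h, and a minimum of 200 gave 115 and 168 at 6 h and 14 and 18 at 24 h. With that minimum 88 and 188 genes differed between lines at every time. A pseudocount of 5 gave 139 and 41 at 6 h and 366 and 110 at 24 h for induction, 48 and 123 at 6 h and 13 and 13 at 24 h in tet-control, and 68 and 168 between lines. A 1.5-fold threshold gave 1054 and 362 at 6 h and 1708 and 1125 at 24 h for induction, 919 and 890 at 6 h and 229 and 190 at 24 h in tet-control, and 421 and 639 between lines. The own change of tet-ZFP36L1 alone gave 647 and 250 at 6 h, and the same-time difference between lines gave 730 and 612 at 6 h and 991 and 1061 at 24 h. Requiring the same-time difference as well left 176 and 49 at 6 h and 386 lower at 24 h. Without genes that differed at 0 h, 54 were higher at 6 h. Plain CPM gave 384 lower at 24 h.

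The ZFP36L1 difference was 4.92 at 6 h and 5.23 at 24 h with the deposited TPM and 4.18 at 24 h with plain CPM, against 3.89 and 4.01. With a pseudocount of 5, medians were -0.87 at 6 h and -0.66 at 24 h for ZFP36-family targets, -1.31 at 6 h for NF-kB cytokines and -0.26 at 6 h for basal urothelial genes. The G1/S median at 24 h was -0.15 with the deposited TPM and the G2/M median at 24 h -0.76 with plain CPM. For genes with 2 or more AU-rich elements the median was -0.38 at 6 h with the longest 3' UTR, -0.47 at 6 h with the nonamer and -0.18 at 24 h with the deposited TPM. Genes with few counts are the least precise, and 1 library per group limits every value.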

Other observations

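The tests for AU-rich elements and for shared sequence words were written before their results were seen; the tests on doxycycline and on promoter integration were chosen afterwards, and the matching of the last was changed after a first result.

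Among protein-coding genes with a mean count of at least 500, 10 other than ZFP36L1 were at least 4-fold higher at both times in tet-ZFP36L1, in both the induction difference and the line's own change, and 0 with the lines exchanged. They were ROBO2, DLG3, GLE1, KDM4A, CYTH1, LCP1, MAST2, KDM3B, KNL1 and STK4, on 9 chromosomes; the set, and the count minimum that defines it, were chosen after the values were seen. The median difference was 3.06 at both times. The 40 nearest measured genes had a median of -0.04 at 6 h, and 2 of them were at 1 or more.

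Doxycycline itself does not account for the set: of 15 genes raised as much in tet-ZFP36L1 but chosen without regard to tet-control, which include these 10, the larger of the 2 median changes in tet-control was 0.15, though 4 of the 15, LCP1 among them, were at least 2-fold higher there at 6 h. Reads of the ZFP36L1 transgene do not account for them through shared sequence either, since the highest share of a gene's 31-base words found in a ZFP36L1 transcript was 0.0%. A candidate explanation is that copies of the inducible promoter integrated in or near some of these genes, which would change the proportions of their transcripts. The median change of transcript shares from 0 h to 6 h was 0.17, at percentile 97.56 (sampling error 0.15) of sets matched on the 0 h count, and at 99.98 of sets matched on the mean count, which allows less for noisy shares at low counts. The first value is within its sampling error of the upper bound of the central 95%, so this cannot be told apart from regulation downstream of ZFP36L1; reads across vector and genome junctions would be needed.

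The lower level of genes with TATTTAT could follow from the element or from A/U-rich sequence in general. With 2 or more copies the median lay at percentile 0.0 of matched sets at 6 h and at 0.0 at 24 h, but both permuted 7-mers lay at 0.0 too, so the percentile does not separate the element from its permutations. The larger shift of the permuted 7-mers was 0.38 of the shift of TATTTAT at 6 h, below the bound of 0.5, so these permutations went with a smaller shift than the element. Gene sets were not matched on A/U content and the share has no error estimate, so composition of the 3' UTR is not excluded at that time. At 24 h the share was 0.66, above that bound and below 1, so element and composition cannot be told apart there either. Genes with a permuted 7-mer that also carry TATTTAT were not left out, so neither share measures composition alone. Neither result measures mRNA decay.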
